A study of Bos taurus with 18 samples.

How the data were processed

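RNA was measured in pieces of caput, corpus and cauda epididymidis from 6 Holstein bulls, 3 of high and 3 of medium-low fertility, which gave 18 arrays in 6 groups of 3. Per the labels, the bulls were 51 to 71 months old, and fertility was the share of cows that did not return to service within 56 days, from 282 to 486 first inseminations per bull, adjusted for herd, month, cow age, technician and semen price. Per the labels' protocols, epididymides came from a slaughterhouse on ice and were dissected into the segments, and small pieces were snap-frozen. Total RNA was column-purified with DNase treatment, and 200 ng per sample was labelled with biotin by a whole-transcript kit. The values are deposited log2 signals of a bovine gene array, 1 per probe set and array, which the authors normalized with RMA per the submitters' processing notes. RMA corrects background, makes the probe distributions of all arrays alike and summarises the probes of a set to 1 log2 value. The same notes list Affymetrix Expression Console and Partek 6.5 without their role. In the values themselves, no entry was missing or negative, the range was 2.56 to 14.5 and the column medians lay between 7.26 and 7.39, which is the range of such log2 values. No detection call comes with the values used here, so a group of low signal can be at background and differences against it are not exact folds. No probe set was filtered out and no further normalization was applied.

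Of 26773 probe sets, 18457 named 1 gene, 688 named several and 7628 had no gene name in the sources used here. The named ones covered 18010 genes, of which 401 had several probe sets. The current reference table of bovine genes, matched by gene number, held 17996 of the 1-gene probe sets and changed 0 symbols. The values of 297 probe sets were identical to another's on all arrays.

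All 18 arrays entered 1 model of 6 group means in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation of the spread. The fertility difference was taken within each segment as medium-low minus high, 3 arrays against 3. Segment differences, each named segment minus the segment it is set against, were averaged with equal weight over both fertility groups, 6 arrays against 6. The same segment differences were also taken inside each fertility group. Whether the fertility difference varied between the segments was tested by limma's F test of 2 interaction contrasts. The fertility difference over the segments used 6 means, each of the 3 arrays of 1 fertility group and replicate number, since 6 bulls gave 18 arrays and arrays of 1 bull are not independent animals. The labels do not say that a replicate number marks a bull. Every p of a gene is limma's, adjusted by the Benjamini-Hochberg method over all 26773 probe sets, and the threshold was 0.05. Standard errors (SE) are those of the model and standard deviations (SD) are between arrays of a group.

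For gene groups, 34 lists were fixed for the tissue, for processes of the duct and for other cell types that a piece of epididymis can hold. Each list with at least 5 measured genes was tested with limma's camera test at a preset correlation of 0.01, which asks whether the genes of a list moved one way compared with all other genes. The Benjamini-Hochberg method was applied over the lists of a comparison, and a gene was represented by its brightest probe set. The test was repeated with a correlation estimated from the data, and limma's fry test was run beside it. For each list, members past the threshold were counted over all genes and adjusted over the list alone. One list held 10 genes recalled as named by the study itself, of which 9 were measured, and its membership was not checked against a source.

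Named genes followed a rule. Per comparison, the 10 higher and the 10 lower genes with the largest log2 difference were taken among 1-gene probe sets that passed the threshold and whose compared arrays did not overlap. A fertility comparison with fewer than 10 was filled to 5 per direction by the largest differences with an unadjusted p under 0.05 and no overlap, and these are said not to pass. Up to 4 members of each described list and every measured gene of the recalled list were added. Items named outside the rule are said to have been chosen after their values were seen. The comparisons, the tests, the lists, this rule and most other settings were chosen before the data were examined.

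The other settings chosen then left out dim probe sets, subtracted array medians, applied quantile or cyclic loess normalization on top, weighted the arrays, used a trended and robust prior, replaced the adjusted p by an unadjusted p under 0.05 with at least a 2-fold difference, kept 1 probe set per gene, fitted the arrays of a segment alone, took the segment differences of each fertility group alone from the same model, added the replicate number as a block (statmod 1.5.0) and left out each array in turn. Settings without a pair of caput arrays, and 1 with corpus and cauda arrays only, were added after the data were seen.

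The model was tested on simulated data. Each probe set was drawn around its mean over all arrays, with independent normal noise of its residual SD in the model. Of these, 100 were changed by 2-fold and 100 by 4-fold. All groups thus had 1 spread, unlike the real arrays. There the SD of the difference between 2 replicates was 0.416 to 0.667 in medium-low caput and 0.305 to 0.314 in high caput. The recovery below need not hold for caput. The fertility difference recovered 74% of the 2-fold and 98% of the 4-fold changes in caput, 77% and 94% in corpus, 74% and 95% in cauda, and 88% and 99% over the segments. The interaction recovered 59% and 86%. Corpus against caput recovered 92% and 100%, cauda against caput 91% and 99%, and cauda against corpus 93% and 100%. Between 5 and 16 of 26573 unchanged probe sets were called. In cauda against caput, a list of 20 shifted genes was called in 5 of 5 draws with either correlation. Of 170 tests of unshifted lists, 34 lists in 5 draws, 1 gave a call with the preset correlation and 0 with the estimated one. Genes were drawn independently, so these draws cannot tell how the preset correlation serves lists whose genes vary together. Arrays carry no read depth, so their number and their spread limit the precision. Figures were drawn with matplotlib 3.10.9.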

Results

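Gene expression was measured in the epididymis, the duct in which sperm leaving the testis mature and are stored, of 6 Holstein bulls with records of fertility. Arrays covered its 3 segments, the caput (head), corpus (body) and cauda (tail), in 3 bulls of high and 3 of medium-low fertility, which gave 6 groups of 3 arrays. Each of the 18 arrays gave 1 log2 value for each of 26773 probe sets, and their number limits the precision of every comparison. Pairs of arrays of a group correlated across probe sets at 0.989 to 0.990 in high caput, 0.988 to 0.989 in high corpus and 0.986 to 0.989 in high cauda. The range was wider in medium-low corpus, 0.979 to 0.990, and medium-low cauda, 0.978 to 0.985. It was widest in medium-low caput, where the pairs lay between 0.951 and 0.981. The SD of the difference between 2 replicates was 0.305 to 0.314 in high caput and 0.416 to 0.667 in medium-low caput.

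The study compared the segments, and among the named genes GDF3 rose most and GPX5 fell most from caput to corpus. GDF3, a ligand of the TGF-beta family, stood at 4.83 ± 0.151 (SD, n = 6) in caput and at 12.04 ± 0.349 (SD, n = 6) in corpus (SE of the difference 0.149, limma adjusted p = 1.26e-13). CD52, a glycopeptide that the epididymis passes to sperm, rose 24.8-fold, from 7.76 ± 0.641 to 12.39 ± 0.221 (SD, n = 6 each). The carboxylesterase CES5A rose by 6.37 (log2, SE 0.379), the ecto-nucleotidase ENTPD3 by 5.80 (SE 0.271), the sodium channel subunit SCN9A by 27.9-fold and the glutathione peroxidase GPX2 by 4.32 (SE 0.426). LOC523503 rose 128-fold, LOC532207 by 5.10, OR9K2J by 4.62 and C2H2orf80 by 3.89. In the other direction, GPX5, a secreted glutathione peroxidase of the caput, fell by 5.75 (SE 0.596), from 13.66 ± 0.291 to 7.91 ± 1.97 (SD, n = 6 each). GPX6 fell by 5.32 (SE 0.299), the secreted proteins RNASE10 and LCN6 by 5.13 (SE 0.462) and 5.11 (SE 0.324), the protease OVCH2 by 5.10, the scaffold protein PDZK1 by 5.05, LOC506921 by 4.96, the nucleoside transporter SLC28A3 by 4.61, the phosphate transporter SLC34A2 by 4.35 and LOC100296742 by 4.16. For each of these 20 genes the 6 corpus and the 6 caput arrays did not overlap. Some caput means mix unlike arrays. In medium-low caput replicates 1 and 2 GPX2 was at 6.05 and 5.29, against 8.35 to 8.86 in the other caput arrays. C2H2orf80 was at 4.95 and 5.19 against 7.72 to 8.12, and OR9K2J at 4.06 and 5.15 against 5.78 to 8.72. Without both replicates, a setting chosen after the data were seen, GPX2 rose by 3.26, C2H2orf80 by 2.88 and OR9K2J by 3.25.

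Gene groups moved as well between caput and corpus. Of 20 measured genes for secreted and surface proteins of the caput, 9 fell and 3 rose, 10 and 3 adjusted over the list alone, with a median difference of -0.87 (camera adjusted p = 0.00815; adjusted p = 0.145 with an estimated correlation). Cholesterol and fatty acid synthesis was lower, with 13 of 23 genes down and 0 up, 14 and 0 adjusted over the list alone. The desaturase SCD fell by 2.48, NSDHL by 0.97 and LSS by 0.92 (camera adjusted p = 0.000194; adjusted p = 0.63 with an estimated correlation). Of 49 nuclear genes of the respiratory complexes, 20 fell and 5 rose, 23 and 5 adjusted over the list alone. NDUFS7 fell by 0.53, UQCRB by 0.52 and NDUFB5 by 0.50, while COX8A rose by 0.84 (camera adjusted p = 0.00171; adjusted p = 0.647 with an estimated correlation). Interferon-stimulated genes were higher in corpus, 13 of 21 up and 1 down, and as many adjusted over the list alone. MX1 rose by 2.03, MX2 by 1.76, OAS1Y by 1.76 and IFI44 by 1.39 (camera adjusted p = 0.00815; adjusted p = 0.647 with an estimated correlation). Without medium-low caput replicates 1 and 2 this adjusted p was 0.0652. Endothelial genes were higher too, 11 of 19 up and 0 down, and as many adjusted over the list alone. The VEGF receptor KDR rose by 1.60, EMCN by 0.77, ESAM by 0.58 and CLDN5 by 0.54 (camera adjusted p = 0.00262; adjusted p = 0.63 with an estimated correlation).

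Sperm and spermatid transcripts were lower in corpus than in caput. Of 51 measured genes 9 fell and 1 rose, 4 and 1 adjusted over the list alone. GSG1 stood at -1.72, CRISP2 at -1.64, ZPBP at -1.09 and PGK2 at -1.09 (camera adjusted p = 0.00563; adjusted p = 0.807 with an estimated correlation). Of the 9 measured genes recalled, unchecked, as named by the study 4 fell and 7 did adjusted over the list alone. These were the sperm tail gene ODF1 at -1.39 (adjusted p = 0.0453), FAM161A at -0.91 (0.00571), CTCFL at -0.40 (0.0363) and the sorbitol dehydrogenase SORD at -0.39 (0.0144). The list passed as a set (camera adjusted p = 0.0248; adjusted p = 0.737 with an estimated correlation), but if the study named them on these samples they are not independent evidence. Without the medium-low replicate 3 arrays the adjusted p was 0.15 for the spermatid list and 0.166 for the recalled list. The mean of the spermatid list lay 0.94 and 0.76 above its average over all arrays in medium-low caput replicates 2 and 3. It stood at -0.30 on that scale in replicate 1 and at 0.09 to 0.26 in high caput. ODF1 and CTCFL lost their calls without several single arrays, at adjusted p up to 0.112 for ODF1 and 0.094 for CTCFL.

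In all, 8881 probe sets passed between corpus and caput, 5214 higher and 3667 lower, and 483 of the higher and 577 of the lower ones differed by at least 2-fold. The share of higher calls depended on the scaling. It was 58.7% as deposited, 41.1% (3259 higher, 4663 lower) with array medians subtracted and 47.5% (3713 higher, 4111 lower) after cyclic loess, with median shifts of -0.07 and -0.06 (log2). After quantile normalization the share was 54% (4333 higher, 3697 lower), with a median shift of -0.04.

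Cauda against caput gave the most probe sets with at least a 2-fold difference. As lists, smooth muscle, endothelial and fibroblast genes were higher (adjusted p = 0.333, 0.178 and 0.618 with an estimated correlation), and caput secreted proteins and beta-defensins were lower (adjusted p = 0.00962 and 0.0382 with an estimated correlation). LCN6 fell 96.9-fold, from 13.53 ± 0.559 to 6.93 ± 0.302 (SD, n = 6 each; limma adjusted p = 1.57e-09). RNASE10 fell by 5.76 (SE 0.462), SPINLW1, the protease inhibitor also called EPPIN, by 5.75 (SE 0.318), OVCH2 by 5.56, PDZK1 by 5.28, the sialyltransferase ST8SIA6 by 5.27, GLB1L3 by 5.25, SLC28A3 by 5.18, the cystatin CST11 by 4.82 (SE 0.776) and GPX5 by 4.79. The caput means of GLB1L3 and CST11 mix unlike arrays. GLB1L3 was at 8.22 and 8.23 in medium-low caput replicates 1 and 2 and at 12.24 to 12.54 in the other caput arrays. CST11 was at 13.81 and 13.75 against 7.55 to 8.53. Without both replicates, a setting chosen after the data were seen, the difference of CST11 was -3.02. CD52 rose 51.2-fold, to 13.44 ± 0.0765 (SD, n = 6). The orphan receptor GPR50 rose by 5.78 (SE 0.52), the kinase NRK by 5.52 (SE 0.372), the secretoglobin SCGB1D by 5.02, KCNIP3, a calcium sensor that binds potassium channels, by 4.56 (SE 0.156), TKTL1, a relative of transketolase, by 4.41 and the matrix protease MMP7 by 4.24. LOC523503 rose by 6.29, OR9K2J by 5.29 and CES5A by 5.09. Some cauda means mix unlike arrays as well. In medium-low cauda replicate 3 GPR50 was at 8.32, NRK at 8.49 and MMP7 at 7.41. The other cauda arrays lay at 12.39 to 12.65, 10.45 to 11.77 and 9.12 to 11.52. SCGB1D was higher in that array, at 12.16 against 9.06 to 10.94.

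Smooth muscle genes rose in cauda, 19 of 20 measured genes up and 0 down, and as many adjusted over the list alone, with a median of 1.38. SYNPO2 rose by 2.11, SYNM by 1.78, LMOD1 by 1.55 and desmin, DES, by 1.53 (camera adjusted p = 9.13e-11; adjusted p = 0.333 with an estimated correlation). Among endothelial genes 16 of 19 rose and 0 fell, 18 and 0 adjusted over the list alone. EMCN rose by 1.53, PECAM1 by 1.00, EGFL7 by 0.99 and ENG by 0.86 (camera adjusted p = 9.71e-07; adjusted p = 0.178 with an estimated correlation). Fibroblast and matrix genes had 17 of 26 up and 1 down, 18 and 2 adjusted over the list alone. Fibronectin, FN1, rose by 2.23, SFRP4 by 1.56, COL6A3 by 1.55 and COL3A1 by 1.28 (camera adjusted p = 0.000329; adjusted p = 0.618 with an estimated correlation). Immediate early and heat shock genes, which also respond to the handling of tissue, had 20 of 28 up and 1 down, 22 and 1 adjusted over the list alone. CCN2 rose by 3.07, NR4A1 by 2.20 and FOS by 1.95 (camera adjusted p = 1.5e-06; adjusted p = 0.256 with an estimated correlation). Glycolysis and hypoxia genes had 13 of 24 up and 1 down, 14 and 3 adjusted over the list alone. PFKP rose by 1.44, ADM by 1.40 and ALDOA by 1.01 (camera adjusted p = 0.00388; adjusted p = 0.112 with an estimated correlation).

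Proteins known for secretion in the caput and beta-defensins were lower in cauda than in caput. Of 20 caput secreted proteins 12 fell and 2 rose, 14 and 2 adjusted over the list alone, with a median of -1.79 (camera adjusted p = 2.47e-05; adjusted p = 0.00962 with an estimated correlation). Some members rested on medium-low caput replicates 1 and 2. Without both, a setting chosen after the data were seen, LCN9 moved from -2.5 to -0.05 and LCN15 from -1.65 to 0.1. RNASE12 turned from 0.9 to -0.28 and CRISP1 from 0.34 to -0.63, while LCN6 was at -6.6 and -6.39. Beta-defensins, antimicrobial peptides that coat sperm, had 9 of 15 down and 0 up, and as many adjusted over the list alone. DEFB122A fell by 5.24, DEFB116 by 2.73, DEFB114 by 2.57 and DEFB122 by 2.20 (camera adjusted p = 0.00111; adjusted p = 0.0382 with an estimated correlation). Their caput means mix unlike arrays. DEFB122A was at 4.53 and 3.99 in medium-low caput replicates 1 and 2, within its cauda range of 3.83 to 5.52, and at 12.24 to 12.6 in the other 4 caput arrays. DEFB122 was at 5.37 and 5.55 against 8.15 to 9.12, DEFB116 at 8.66 and 9.17 against 10.7 to 10.93, and DEFB114 at 12.69 and 12.62 against 7.8 to 8.45. Without these 2 arrays the differences were -7.93 for DEFB122A, -3.35 for DEFB116, -0.95 for DEFB114 and -3.19 for DEFB122. This setting was chosen after the data were seen. DEFB124 turned round in it, from -1.14 to 0.98. It was at 13.74 and 13.51 in the arrays left out and at 7.09 to 7.55 in the other caput arrays. LAP moved from -0.45 to -0.25 and EBD from -0.49 to -0.35. Genes of protein folding and export in the endoplasmic reticulum had 22 of 29 down and 0 up, 23 and 1 adjusted over the list alone. DNAJB9 fell by 1.27, DNAJB11 by 1.21, SEC11C by 1.11 and SEC61A1 by 0.95 (camera adjusted p = 2.45e-08; adjusted p = 0.256 with an estimated correlation). Genes of ciliated cells had 13 of 28 down and 2 up, and as many adjusted over the list alone. ARMC3 stood at -2.68, LRRIQ1 at -2.03 and FAM161A at -1.91, against DNAH11 at 2.26 (camera adjusted p = 0.00114; adjusted p = 0.386 with an estimated correlation). Cell cycle genes had 10 of 24 down and 1 up, 13 and 1 adjusted over the list alone. BUB1B stood at -1.65 and KIF11 at -1.05, against BUB1 at 0.88 (camera adjusted p = 0.000404; adjusted p = 0.618 with an estimated correlation).

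Germ cell transcripts were lower in cauda than in caput as well. Of 51 sperm and spermatid genes 17 fell and 4 rose, 20 and 5 adjusted over the list alone. CRISP2 stood at -2.09, CLGN at -1.94, GSG1 at -1.91 and ROPN1L at -1.90 (camera adjusted p = 0.000329; adjusted p = 0.647 with an estimated correlation). Of 19 genes of spermatogonia and meiosis 8 fell and 1 rose, and as many adjusted over the list alone, with MEIOB at -1.82 and MAEL at -1.09 (camera adjusted p = 0.0125; adjusted p = 0.618 with an estimated correlation), and the adjusted p was 0.0748 without the medium-low replicate 3 arrays. Of the 9 genes recalled, unchecked, as named by the study 5 fell, 6 adjusted over the list alone, a list that is not independent evidence here. These were FAM161A at -1.91 (adjusted p = 9.53e-06), ODF1 at -1.39 (0.0446), AKAP4, an anchoring protein of the sperm tail, at -1.23 (0.0232), CTCFL at -0.58 (0.00387) and SORD at -0.54 (0.00154). The list gave a camera adjusted p of 0.00388 (adjusted p = 0.509 with an estimated correlation). The call of AKAP4 cauda against caput was lost without medium-low caput replicate 2 (0.0619), medium-low caput replicate 3 (0.0565) or medium-low cauda replicate 3 (0.0547). The call of ODF1 cauda against caput was lost without any of 11 single arrays, at adjusted p up to 0.105. Between cauda and caput 8629 probe sets passed, 4596 higher and 4033 lower, of which 779 and 755 differed by at least 2-fold. The higher calls were 53.3% as deposited, 44.7% (3832 higher, 4745 lower) with array medians subtracted and 48.9% (4287 higher, 4478 lower) after cyclic loess, so the majority turned under these scalings. After quantile normalization the majority stayed higher, at 52.7% (4590 higher, 4123 lower).

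**Figure D1:**
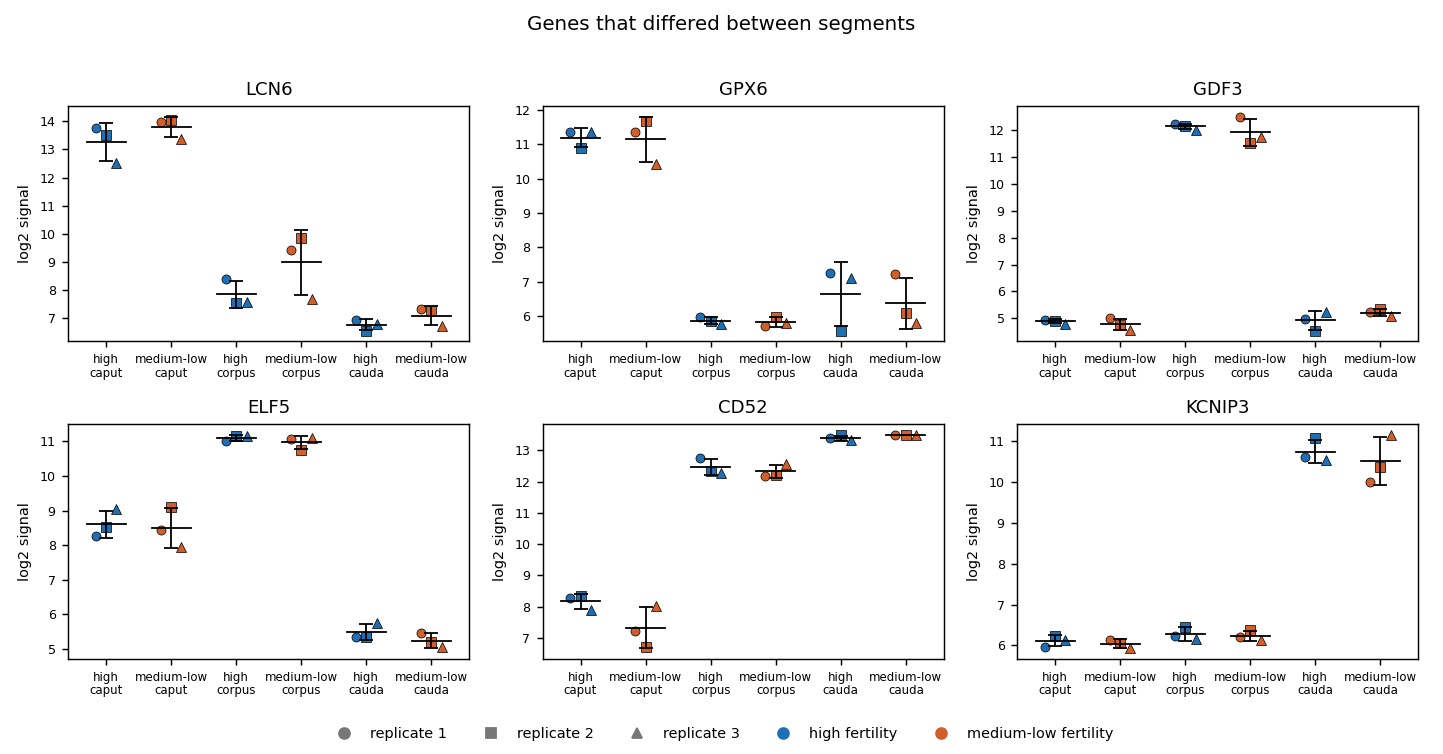
Log2 signal of LCN6, GPX6, GDF3, ELF5, CD52 and KCNIP3 in each array of the 6 groups, with a line for the mean and a bar for the SD of the 3 arrays of a group. GDF3 averages 4.83 in caput, 12.04 in corpus and 5.07 in cauda, while LCN6 averages 13.53 in caput and 6.93 in cauda.

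Among the named genes S100G rose most and GDF3 fell most from corpus to cauda. S100G, the calcium-binding protein calbindin-D9k, rose 55.4-fold, from 5.82 ± 0.374 to 11.62 ± 0.275 (SD, n = 6 each; limma adjusted p = 7.9e-07). GPR50 rose by 5.78, NRK by 5.35, SCGB1D by 4.84, PROM2 by 4.49 and KCNIP3 by 4.38. The cauda means of GPR50, NRK and SCGB1D mix unlike arrays, as given above for medium-low cauda replicate 3. SCNN1A, a subunit of the epithelial sodium channel, rose by 3.83 (SE 0.146), the potassium channel KCNT1 by 3.83 (SE 0.306), CYP11A1, the enzyme that opens steroid synthesis, by 3.71 and NUDT10 by 3.68. GDF3 fell by 6.97 (SE 0.149), and the transcription factor ELF5 fell from 11.04 ± 0.149 to 5.35 ± 0.242 (SD, n = 6 each; adjusted p = 1.17e-11). The glutaminyl cyclase QPCT fell by 5.76 (SE 0.856), ENTPD3 by 5.71, WFDC8 by 4.69, DUOXA1, a partner of dual oxidase, by 4.49, LOC613358 by 4.49, GLB1L2 by 4.42, SPINLW1 by 4.41 and LOC532207 by 24.3-fold.

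As between cauda and caput, smooth muscle genes rose in cauda over corpus, 19 of 20 up and 0 down, and as many adjusted over the list alone. SYNPO2 rose by 1.99, SYNM by 1.94, ACTG2 by 1.49 and PDLIM3 by 1.48 (camera adjusted p = 4.22e-13; adjusted p = 0.389 with an estimated correlation). Cholesterol and fatty acid synthesis rose, 13 of 23 genes up and 0 down, and as many adjusted over the list alone. SCD rose by 2.47, SREBF1 by 1.15, ACACA by 0.94 and FDFT1 by 0.86 (camera adjusted p = 4.86e-05; adjusted p = 0.389 with an estimated correlation). Respiratory complex genes had 17 of 49 up and 1 down, 21 and 1 adjusted over the list alone. NDUFS7 rose by 0.66, UQCRB by 0.64 and NDUFA13 by 0.48 (camera adjusted p = 5.14e-05; adjusted p = 0.455 with an estimated correlation). Immediate early and heat shock genes had 16 of 28 up and 1 down, 17 and 2 adjusted over the list alone. NR4A3 and CCN2 both rose by 2.86 (camera adjusted p = 1.76e-05; adjusted p = 0.389 with an estimated correlation). Fibroblast genes had 10 of 26 up and 2 down, 10 and 3 adjusted over the list alone. FN1 rose by 1.62 and ASPN by 1.42 (camera adjusted p = 0.00436; adjusted p = 0.623 with an estimated correlation). Endothelial genes had 8 of 19 up and 1 down, 9 and 1 adjusted over the list alone. TEK stood at 0.71 and KDR at -1.12 (camera adjusted p = 0.00942; adjusted p = 0.511 with an estimated correlation). Ion and water transport had 8 of 29 up and 2 down, 9 and 2 adjusted over the list alone. SCNN1A stood at 3.83, SLC26A3 at 2.70 and the chloride channel CFTR at 2.59 against SLC26A4 at -2.19 (camera adjusted p = 0.0465; adjusted p = 0.253 with an estimated correlation). That call was lost with array medians subtracted (0.0591) and without the arrays of high replicate 2 (0.058), high replicate 3 (0.0604), medium-low replicate 1 (0.0508) or medium-low replicate 3 (0.0772).

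Protein folding and export was lower in cauda than in corpus, 15 of 29 genes down and 0 up, 19 and 1 adjusted over the list alone. DNAJB9 fell by 0.90 and PDIA4 by 0.88 (camera adjusted p = 5.14e-05; adjusted p = 0.511 with an estimated correlation). Interferon-stimulated genes had 8 of 21 down and 0 up, 9 and 0 adjusted over the list alone. USP18 and MX1 both stood at -1.77 (camera adjusted p = 0.0078; adjusted p = 0.511 with an estimated correlation). Caput secreted proteins had 6 of 20 down and 0 up, and as many adjusted over the list alone. The receptor kinase ROS1 stood at -2.47, LCN6 at -1.48 and clusterin, CLU, at -1.35 (camera adjusted p = 0.018; adjusted p = 0.197 with an estimated correlation). Beta-defensins had 7 of 15 down and 1 up, 7 and 2 adjusted over the list alone. DEFB7 stood at -2.39 and DEFB110 at 1.36 (camera adjusted p = 0.011; adjusted p = 0.197 with an estimated correlation). Cell cycle genes had 6 of 24 down and 1 up, 14 and 1 adjusted over the list alone (camera adjusted p = 0.00388; adjusted p = 0.623 with an estimated correlation). T and natural killer cell genes had 3 of 26 down and 0 up, and as many adjusted over the list alone, ZAP70 at -0.43, CXCR6 at -0.39 and SH2D1A at -0.34 (camera adjusted p = 0.011; adjusted p = 0.623 with an estimated correlation). Tight junction genes had 6 of 22 down and 1 up, and as many adjusted over the list alone. CLDN4 stood at -1.98, PARD6B at -0.70 and CLDN10 at 2.56 (camera adjusted p = 0.0272; adjusted p = 0.511 with an estimated correlation). Ciliated cell genes had 7 of 28 down and 3 up, 8 and 3 adjusted over the list alone (camera adjusted p = 0.0269; adjusted p = 0.623 with an estimated correlation). Without the high replicate 3 arrays the adjusted p was 0.0602 for tight junctions and 0.0518 for ciliated cells. Without the medium-low replicate 1 arrays it was 0.0508 for tight junctions, and without those of replicate 2 it was 0.0887 for ciliated cells. Of the genes recalled, unchecked, as named by the study FAM161A fell, at -1.0 (adjusted p = 0.00396), which was 1 of 9 both over all genes and adjusted over the list alone, and this list is not independent evidence. The list did not pass as a set (camera adjusted p = 0.437).

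Between cauda and corpus 6511 probe sets passed, 3227 higher and 3284 lower, of which 540 and 478 differed by at least 2-fold. The higher calls were 49.6% as deposited, 56.2% (3490 higher, 2725 lower) with array medians subtracted and 54.3% (3433 higher, 2890 lower) after cyclic loess. Quantile normalization gave 51.5% (3312 higher, 3122 lower). Within the high fertility group, 5240 probe sets passed between corpus and caput, 6073 between cauda and caput and 3881 between cauda and corpus. Within the medium-low group the counts were 4731, 5481 and 2715. These pairs of counts are not a test of a difference between the fertility groups. In medium-low bulls they were 2841 for corpus against caput and 3385 for cauda against caput without medium-low caput replicates 1 and 2.

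**Figure D2:**
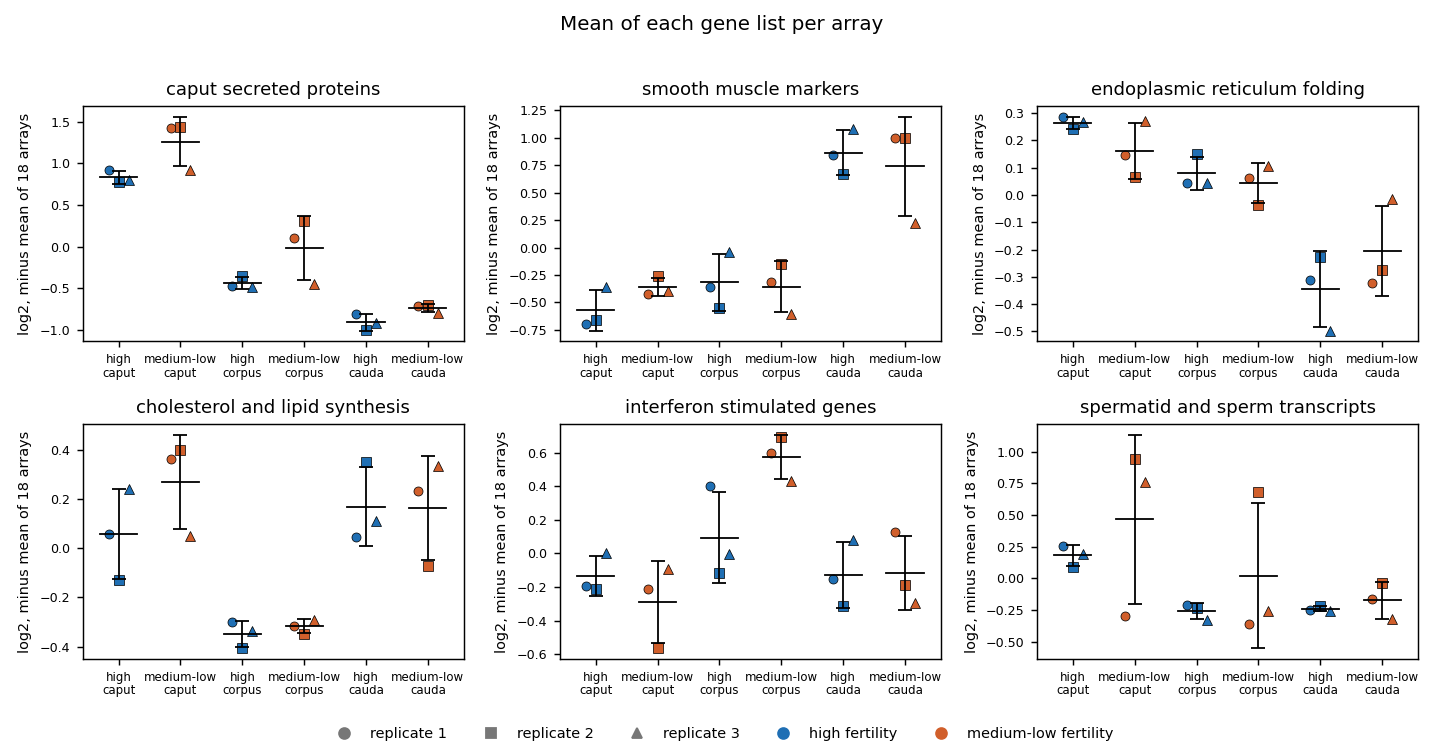
Mean log2 signal of 6 gene lists in each array, minus the list's mean over the 18 arrays, for the 6 groups, with a line for the group mean and a bar for the SD of 3 arrays. Smooth muscle genes lie 0.22 to 1.08 above the average in the cauda arrays, and spermatid genes stand at 0.94 and 0.76 in medium-low caput replicates 2 and 3 and at 0.68 in medium-low corpus replicate 2.

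The main question of the study was whether the epididymis of medium-low fertility bulls differs from that of high fertility bulls. In caput CCDC196, a gene for a coiled-coil protein, had the lowest adjusted p of the named genes, at 4.26 ± 0.209 in medium-low and 6.64 ± 0.152 in high arrays (SD, n = 3 each), a fall of 2.39 with SE 0.184 (limma adjusted p = 2.25e-05). S100G averaged 10.65 ± 2.18 in medium-low and 6.56 ± 0.298 in high caput (SD, n = 3 each; log2 difference 4.08, SE 0.69, adjusted p = 0.0427), with medium-low arrays at 11.86, 11.95 and 8.13. The adhesion protein VSIG1 rose by 2.75 (SE 0.443, adjusted p = 0.037), the polarity scaffold PALS2 by 1.57 (0.043), the lipocalin relative LCNL1 by 1.48 (SE 0.231, 0.0365), the transcription cofactor LMO2 by 1.39 (0.043), TMEM116 by 1.30 (0.0456) and the coronin CORO2B by 1.04 (0.0427). TTC7A rose by 0.85, RAB19 by 0.81 and ENDOD1 by 0.76. Lower in medium-low caput were the glutathione transferase GSTA2 at -1.85 (SE 0.318, 0.0427), the calcium sensor DOC2B at -1.69 (SE 0.27, 0.0365), the antimicrobial cathelicidin CATHL4 at -1.61 (0.0427) and the complement component C9 at -1.53 (SE 0.229, 0.03). The channel subunit CACNG6 followed at -1.51, the microRNA gene MIR2488 at -1.45, the glypican GPC5 at -1.37, PODN at -1.36 and SAPCD1 at -1.35.

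A probe set with no gene name in the sources used here, 12708857, had the lowest adjusted p in caput and was chosen after its values were seen. It stood at 9.0 ± 0.155 in high caput and 5.84 ± 0.316 in medium-low caput (SD, n = 3 each; log2 difference -3.16, SE 0.162, limma adjusted p = 1.42e-07), and at 4.95 to 5.51 on average in the 4 corpus and cauda groups.

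The 3 medium-low caput arrays were unlike each other. Replicates 1 and 2 carried POSTN, a matrix protein, at 12.91 and 13.37 against 6.38 in replicate 3 and 5.24 to 5.51 in high caput. The lipocalin LCN9 was at 13.8 and 13.54 against 6.31 and 6.18 to 6.46, and CST11 at 13.81 and 13.75 against 8.36 and 7.55 to 8.53. The opposite held for QPCT, at 4.17 and 5.3 in replicates 1 and 2, 11.56 in replicate 3 and 11.29 to 12.09 in high caput, for WFDC8, at 8.22 and 7.4 against 13.23 and 13.2 to 13.4, and for the carboxypeptidase CPM, at 5.42 and 5.4 against 11.03 and 10.73 to 11.4.

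**Figure D3:**
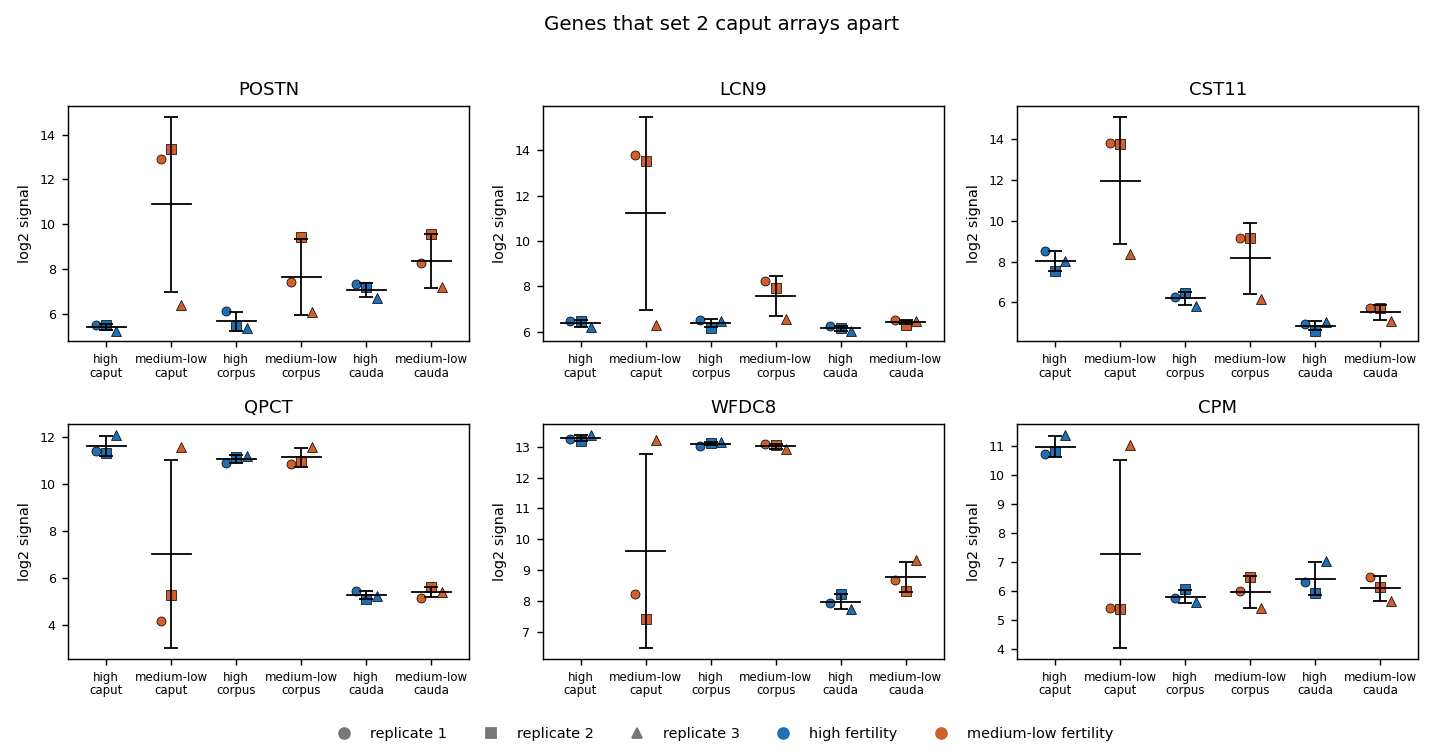
Log2 signal of POSTN, LCN9, CST11, QPCT, WFDC8 and CPM in each array of the 6 groups, with a line for the mean and a bar for the SD of 3 arrays. POSTN stands at 12.91 and 13.37 in medium-low caput replicates 1 and 2 and at 6.38 in replicate 3, while high caput lies between 5.24 and 5.51.

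In caput 4 gene groups passed, with few single members past the threshold over all genes. Antioxidant enzymes were lower in medium-low caput, 1 of 37 genes down and 0 up, 9 and 1 adjusted over the list alone. GSTA2 was the 1 that passed, and GPX3 at -1.96 (adjusted p = 0.0816), GPX2 at -1.84 (0.102) and NQO1 at -1.35 (0.0655) did not (camera adjusted p = 0.00241; adjusted p = 0.882 with an estimated correlation). Respiratory complex genes had a median of -0.11, 0 of 49 passing and 1 down adjusted over the list alone, with NDUFA4 at -0.79 (0.0655) not passing (camera adjusted p = 0.00804; adjusted p = 0.882 with an estimated correlation). Macrophage genes had a median of 0.33, 0 of 20 passing and 6 up adjusted over the list alone, with MS4A7 at 2.42 (0.0713), FCGR3A at 0.67 and C1QB at 0.59 not passing (camera adjusted p = 0.00241; adjusted p = 0.882 with an estimated correlation). Without medium-low caput replicates 1 and 2 the camera adjusted p was 0.506 for antioxidant, 0.0835 for respiratory and 0.0626 for macrophage genes. Sperm and spermatid genes had a median of 0.33, 0 of 51 passing and 1 up adjusted over the list alone, with FSCN3 at 0.76, HSPA1L at 0.74, LDHC at 0.69 and ZPBP at 0.68 not passing (camera adjusted p = 0.00367; adjusted p = 0.882 with an estimated correlation). The mean of that list was -0.30, 0.94 and 0.76 in medium-low caput replicates 1, 2 and 3, and 0.26, 0.09 and 0.19 in high caput, relative to all arrays. Its camera adjusted p was 0.173 without the medium-low replicate 2 arrays and 0.377 without those of replicate 3. None of the 9 genes recalled, unchecked, as named by the study passed in caput, with differences from -0.34 for SORD (adjusted p = 0.237) to 0.54 for AKAP4.

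In caput 57 probe sets passed, 16 higher and 41 lower in medium-low bulls, and 5580 had an unadjusted p under 0.05. This count rested on single arrays: it was 4702 without medium-low caput replicate 3, 4 without replicate 1, 3 without replicate 2, and 6, 2 and 23 without high caput replicates 1, 2 and 3. Without medium-low caput replicates 1 and 2 it was 3, of which 2 were among the 57, and without replicates 2 and 3, which are high in spermatid transcripts, it was 3511. The S100G fertility difference in caput had an adjusted p of 0.0908, 0.136 and 0.0941 without high caput replicates 1, 2 and 3, of 0.108 and 0.181 without medium-low caput replicates 1 and 2, and of 0.426 without both of the latter (log2 difference 1.56). The VSIG1 fertility difference in caput had an adjusted p of 0.0908, 0.123, 0.0821, 0.108 and 0.161 without the same single arrays. CCDC196 passed in each of the 17 other settings run, at -2.52 to -2.28. Both filters of dim probe sets removed CCDC196, so they are not among these settings and did not test it. Each of the other 19 genes named as passing in caput lost its call in 6 to 11 of the 17 to 19 settings it was run in. PALS2 lost it in 9, LCNL1 in 7, LMO2 in 8 and TMEM116 in 10 of 19. Their differences were smallest, at 0.64, 0.82, 0.75 and 0.58, without medium-low caput replicates 1 and 2 (adjusted p = 1, 0.828, 1 and 1).

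In corpus CCDC196 was again lower in medium-low bulls, at 4.27 ± 0.0156 against 5.84 ± 0.136 (SD, n = 3 each; log2 difference -1.57, SE 0.184, limma adjusted p = 0.0109). It was the only probe set of 26773 that passed. An unadjusted p under 0.05 was found for 1182, or 4.4%, no more than a set without any difference would give. Genes next in size did not pass: the joint lubricant PRG4 at 1.49 (adjusted p = 1), the interferon-induced MX1 at 1.38 (0.578), IFI27 at 1.36 (0.578) and IFI44 at 1.25 (1), and LOC100296742 at 1.33 (1). On the other side TMC2 stood at -1.89 (0.0983), TSPAN1 at -1.85 (1), GARNL3 at -1.27 (0.367) and the cytokine IL10 at -1.04 (1). The CCDC196 fertility difference in corpus had an adjusted p of 0.0813, 0.0627 and 0.0681 without high corpus replicates 1, 2 and 3, and of 0.0533 and 0.0923 without medium-low corpus replicates 1 and 2. Without each of the 3 high arrays or medium-low replicate 2 the count was 0, without medium-low replicate 1 it was 1, a different probe set, and without replicate 3 it was 7.

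In corpus 7 gene groups passed as sets although 0 of their members passed over all genes. Interferon-stimulated genes were higher in medium-low bulls, with a median of 0.33 over 21 genes, 7 up and 0 down adjusted over the list alone, and OAS1Y at 1.41 (camera adjusted p = 3.68e-10; adjusted p = 0.211 with an estimated correlation). The other lists had 0 members past the threshold adjusted over the list alone. Fibroblast genes had a median of 0.36, with POSTN at 1.97, LUM at 0.97, ASPN at 0.73 and FN1 at 0.67 (camera adjusted p = 6.33e-07; adjusted p = 0.552 with an estimated correlation). Spermatid genes had a median of 0.25, with FSCN3 at 0.85, CRISP2 at 0.84 and GSG1 at 0.78 (camera adjusted p = 2.74e-06; adjusted p = 0.62 with an estimated correlation). The mean of the spermatid list was -0.36, 0.68 and -0.25 in medium-low corpus replicates 1, 2 and 3, and -0.33 to -0.21 in high corpus, relative to all arrays. Caput secreted proteins had a median of 0.14, with GPX5 at 2.32, CST11 at 1.96, LCN9 at 1.19 and LCN6 at 1.14 (camera adjusted p = 0.04; adjusted p = 0.211 with an estimated correlation). MHC class II genes had a median of 0.11, with BOLA-DRB3 at 0.45 (camera adjusted p = 0.0482; adjusted p = 0.552 with an estimated correlation). Lower were respiratory complex genes, with a median of -0.10 (camera adjusted p = 2.92e-05; adjusted p = 0.552 with an estimated correlation), and cell cycle genes, with a median of -0.20 and KIF11 at -0.42, BUB1 at -0.40 and MKI67 at -0.38 (camera adjusted p = 0.00122; adjusted p = 0.62 with an estimated correlation).

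Of the 7 calls in corpus, the interferon call alone held when the 3 arrays of any 1 replicate number were left out. Without the medium-low replicate 2 arrays the adjusted p was 0.987 for spermatid, 0.0959 for fibroblast, 0.234 for respiratory and 0.311 for caput secreted genes. The caput secreted list also lost its call without high replicate 1 (0.113), high replicate 3 (0.164) and medium-low replicate 1 (0.101), and cell cycle genes without high replicate 2 (0.0764) and medium-low replicate 3 (0.182). MHC class II genes lost it without high replicate 1 (0.0849), high replicate 2 (0.185), medium-low replicate 1 (0.159) and medium-low replicate 3 (0.322), and without medium-low caput replicates 1 and 2 (0.103).

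In cauda 3 probe sets passed, each lower in medium-low bulls. MUC1, a mucin of the epithelial surface, stood at 6.35 ± 0.431 against 8.61 ± 0.757 (SD, n = 3 each; log2 difference -2.26, SE 0.296, limma adjusted p = 0.0224). CCDC196 stood at 4.26 ± 0.199 against 6.31 ± 0.46 (log2 difference -2.04, SE 0.184, adjusted p = 0.000364). TLR5, the receptor for bacterial flagellin, stood at 7.30 ± 0.569 against 8.82 ± 0.0906 (SE of the difference 0.22, adjusted p = 0.0453). Genes that did not pass included TNN at 2.03 (adjusted p = 0.682), the carbonic anhydrase CA3 at 1.12 (0.531), MMD2 at 1.11 (0.588), LOC100297236 at 1.02 (0.588), SLC35F3 at 0.95 (0.364), the R-spondin receptor LGR5 at -2.28 (0.245) and PCDHB1 at -2.06 (0.364). Genes of protein folding and export passed as a set, with a median of 0.14 over 29 genes and 0 members past the threshold over all genes or adjusted over the list alone. SDF2L1 stood at 0.47, CRELD2 at 0.34, MANF at 0.33 and DNAJC3 at 0.30 (camera adjusted p = 0.00309; adjusted p = 0.742 with an estimated correlation). That call was lost without the high replicate 3 arrays (0.334) and without the medium-low replicate 3 arrays (0.407).

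In cauda 1555 probe sets, or 5.8%, had an unadjusted p under 0.05, against 20.8% in caput and 4.4% in corpus. MUC1 had an adjusted p of 0.102 and 0.161 without high cauda replicates 1 and 3, 0.138 and 0.164 without medium-low cauda replicates 2 and 3, and 0.0897 without medium-low caput replicates 1 and 2. With the cauda arrays alone it had 0.638. TLR5 had 0.135, 0.154 and 0.171 without high cauda replicates 1, 2 and 3, 0.108 without medium-low cauda replicate 2 and 0.111 without medium-low caput replicates 1 and 2. The TLR5 fertility difference in cauda also lost its call with quantile normalization on top (0.0552), with array weights (0.0608) and with the cauda arrays alone (0.638). With the replicate number as a block it did not pass either. In all, TLR5 lost the call in 10 of the 17 other settings run. The count of passing probe sets was 1, 4 and 1 without high cauda replicates 1, 2 and 3, and 5, 1 and 2 without medium-low cauda replicates 1, 2 and 3. CCDC196 passed in 15 of 16 other settings, and its adjusted p was 0.638 with the cauda arrays alone. The filters of dim probe sets, which removed it, are not among these settings.

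**Figure D4:**
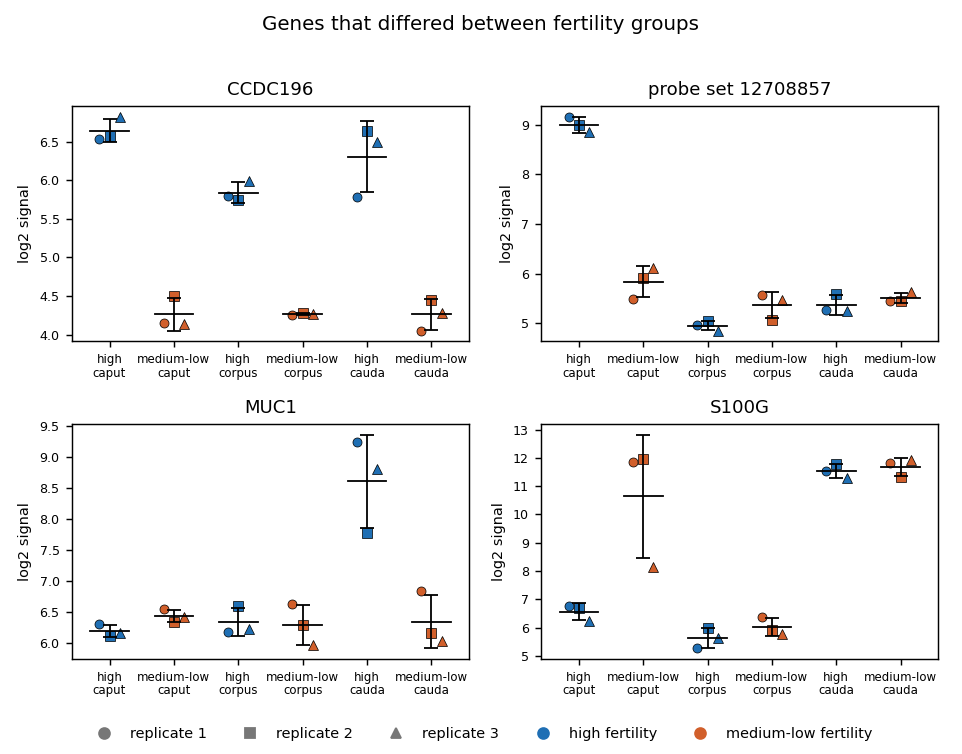
Log2 signal of CCDC196, probe set 12708857, MUC1 and S100G in each array of the 6 groups, with a line for the mean and a bar for the SD of 3 arrays. CCDC196 lies between 5.74 and 6.82 in the 9 high arrays and between 4.05 and 4.5 in the 9 medium-low arrays.

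Over the segments CCDC196 was the 1 probe set that passed, at 4.26 ± 0.133 in medium-low and 6.26 ± 0.206 in high bulls (SD of 3 means each; log2 difference -2.0, SE 0.123, limma adjusted p = 0.0342). Each of the 9 medium-low arrays lay below each of the 9 high arrays. Other large differences did not pass, each at an adjusted p of 0.537: POSTN at 2.91, LCN9 at 2.11, GCNT4 at 1.92, S100G at 1.54 and CRYBA4 at 1.46 were higher on average, and CPM at -1.30, C25H16orf89 at -1.28, NXPE2 at -1.28 and LOC532114 at -1.26 lower. In all of these medium-low caput replicates 1 and 2 stood apart, though in LOC532114 only at 4.78 and 4.85 against 5.66 in replicate 3. GCNT4 was at 12.73 and 12.26 against 5.79 in replicate 3, CPM at 5.42 and 5.4 against 11.03, NXPE2 at 4.31 and 5.04 against 9.9, and C25H16orf89 at 6.74 and 6.9 against 12.35. With corpus and cauda arrays only, a setting chosen after the data were seen, the difference was 1.63 for POSTN, 0.73 for LCN9, 0.39 for GCNT4, 0.27 for S100G and 0.10 for CRYBA4. It was -0.10 for CPM, -0.065 for NXPE2 and 0.06 for C25H16orf89, against -1.45 for LOC532114. Without the means of high replicates 1, 2 and 3 CCDC196 had adjusted p of 0.0593, 0.27 and 0.244, without those of medium-low replicates 1 and 2 it had 0.328 and 0.115, and with corpus and cauda arrays only 0.106. Over the segments 2476 probe sets had an unadjusted p under 0.05, and the count of passing ones was 462 without medium-low replicate 3.

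Gene groups that passed over the segments numbered 5, with 0 members past the threshold over all genes or adjusted over the list alone. Lower in medium-low bulls were respiratory complex genes, with a median of -0.08 (camera adjusted p = 0.000154; adjusted p = 0.9 with an estimated correlation), and antioxidant enzymes, with a median of -0.10 and GPX2 at -0.86 and GSTT1 at -0.86 (camera adjusted p = 0.00899; adjusted p = 0.9 with an estimated correlation). Higher were spermatid genes, with a median of 0.21 (camera adjusted p = 0.000154; adjusted p = 0.9 with an estimated correlation), fibroblast genes, with a median of 0.23 (camera adjusted p = 0.00899; adjusted p = 0.9 with an estimated correlation), and macrophage genes, with a median of 0.17 (camera adjusted p = 0.0408; adjusted p = 0.9 with an estimated correlation). Without the medium-low replicate 2 means the adjusted p was 0.508 for spermatid, 0.397 for fibroblast, 0.0798 for antioxidant and 0.0582 for respiratory genes. Fibroblast genes also lost the call without high replicate 1 (0.115) or 2 (0.115), and macrophage genes without high replicate 1 (0.0799), high replicate 2 (0.115) or medium-low replicate 1 (0.343). Among the genes recalled, unchecked, as named by the study 0 of 9 passed in corpus, in cauda or over the segments, with SORD at -0.69 in cauda (adjusted p = 0.406) and -0.38 over the segments (0.537).

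Whether the fertility difference varied between segments was tested directly, and 1 probe set passed, 12708857, with no gene name in the sources used here. Its fertility difference was 3.58 (SE 0.228) higher in corpus than in caput and 3.30 higher in cauda than in caput (limma adjusted p of the F test 3.57e-06). It averaged 9.0 in high caput and 4.95 to 5.84 in the other 5 groups. The difference between cauda and corpus did not pass, at -0.27 (adjusted p = 1). In total 2354 probe sets had an unadjusted p under 0.05 for the interaction. The count of passing ones was 2359 without medium-low caput replicate 3, and 2 without high cauda replicate 2, without medium-low cauda replicate 3 or without medium-low caput replicates 1 and 2.

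Of the 34 lists, 12 passed in none of the 7 comparisons above. Their lowest camera adjusted p values were 0.057 for B and plasma cells, 0.0571 for acute inflammation, 0.0635 for basal cells, 0.07 for sorbitol and fructose metabolism, 0.137 for corpus and cauda secreted proteins, 0.155 for protease inhibitors, 0.23 for nerve and Schwann cells, 0.253 for androgen and steroid genes, 0.287 for HOX genes, 0.393 for clear and narrow cells, 0.441 for blood and 0.527 for adipocytes. The nerve and Schwann cell list passed in an interaction contrast (0.0306; adjusted p = 0.494 with an estimated correlation) and did not in 7 of 8 settings with arrays left out. The preset correlation gave 52 calls over the 7 comparisons, and 2 of them held with an estimated correlation, caput secreted proteins and beta-defensins in cauda against caput. Without probe sets below the median signal 38 calls passed, a count that also takes in any list without a call before. The call of beta-defensins in cauda against caput did not pass (0.0671). In that setting spermatid (0.462), ciliated cell (0.893) and cell cycle genes (0.128) did not pass in cauda against caput, nor caput secreted (0.106), spermatid (0.106) and respiratory genes (0.0726) in corpus against caput. In cauda against corpus beta-defensins (0.513), ciliated cell (0.691), fibroblast (0.0556) and T and natural killer cell genes (0.154) did not pass there. Among fertility calls, antioxidant (0.106), respiratory (0.219) and spermatid genes (0.388) in caput, MHC class II (0.0784) and cell cycle genes (0.0784) in corpus, and antioxidant (0.197) and spermatid genes (0.0684) over the segments did not pass either. By the fry test, which asks whether the genes of a list moved one way without comparing them with other genes, the fertility call that remained was that of antioxidant genes in caput. The adjusted p of the other fertility calls was 0.116 to 0.789 by fry, and those of spermatid genes in corpus against caput (0.148) and of fibroblast and T cell genes in cauda against corpus (both 0.055) were lost too.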

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

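The tests of spermatid transcripts, of arrays from another segment, of mixed RNA and of the normalization of CCDC196, and the settings without a pair of caput arrays, were chosen only after the result was seen. The gene list for a proximal caput and the neighbours of CCDC196 were chosen before their own values were seen.

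Medium-low caput replicates 1 and 2 stood apart from the other 4 caput arrays, with POSTN, LCN9 and CST11 high and QPCT, WFDC8 and CPM low. Arrays of another segment are argued against, since 29 genes at least 8-fold higher in high corpus than in high caput had medians of only 0.388 and 0.0654 (log2) above the high caput mean, and 41 such cauda genes 0.272 and 0.281. RNA of a tissue that lacks the caput genes, mixed in, would lower them alike. Of 36 caput genes 16 and 14 fell by over 3, as DEFB122A at -7.90 and -8.43. Another 12 and 14 did not fall by over 1, as GPX5 at 0.53 and 0.43. The bound was 10 such genes in both arrays, and the 9 and 10 genes within 1 missed it in replicate 1. It was met only with the 3 and 4 genes that rose by over 1, added after the values were seen. With these counted, mixed RNA of this kind is argued against. A more proximal piece of the caput is a candidate explanation, because 12 feedback genes of the ERK pathway, which is active in the most proximal caput and of which 3 lay above the median gene in high caput, had medians of 1.58 and 1.01, at percentile 100 of 10000 random lists, but replicate 3 reached 99.7 with a median of 0.137. It leaves unexplained that the corpus arrays of these replicate numbers were also higher than that of replicate 3, with GPX5 at 9.97 and 10.84 against 6.39, CST11 at 9.15 and 9.17 against 6.15, LCN9 at 8.21 and 7.94 against 6.56 and POSTN at 7.41 and 9.42 against 6.07 (genes chosen after their values were seen), while mixed RNA of a tissue that holds the kept genes and fertility itself stay open as untested, and the labels do not give the position along the caput.

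Spermatid transcripts were high in medium-low caput replicates 2 and 3 and in medium-low corpus replicate 2, at 0.751, 0.432 and 0.644 (median log2 above high arrays of the segment), with PRM1 at 13.03 and 13.25 against 12.25 to 12.31 in high caput. Testis tissue carried over stays open, since 14 measured Leydig and Sertoli genes, of which 2 lay above the median gene in high caput, had list medians of 0.108, 0.146 and 0.13, or 14.4%, 33.8% and 20.2% of the spermatid median. That list did not follow the spermatid genes, at 0.223 in medium-low caput replicate 1, where these stood at -0.278, and 0.149 in medium-low cauda replicate 2, but its Leydig hormone INSL3 did, at 7.98, 7.61 and 7.0 against 6.08 in medium-low caput replicate 1 and 5.67 to 6.0 in high caput. Mature sperm alone in the duct would leave the meiosis list low, but it moved by at least 0.229, or 98.1%, 53% and 49.8% of the spermatid median, and as the last share missed the bound of 50% this also stays open. The genes named in these arrays were chosen after their values were seen, and a difference between bulls of the fertility groups was not tested apart from them.

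CCDC196 was lower in each medium-low array than in each high array. The difference over the segments was at least as strong as -2.02 under each of 3 normalizations on top of the deposited values. With medians subtracted, quantile and loess, the median shift of all probe sets was only -0.022, -0.007 and -0.011 (log2). Such small changes to values already normalized with RMA cannot decide whether the normalization of the arrays plays a part, which stays untested. A copy number change that spans neighbouring genes is argued against, since the 10 nearest measured genes in the ARS-UCD2.0 gene table had a median of -0.103 with quartiles of -0.121 and -0.037. A sequence variant under the probes of CCDC196, a change in that gene alone and fertility stay open, as the arrays hold no value that separates them.

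Probe set 12708857 stood out because its fertility difference varied between the segments, at a limma adjusted p of 3.57e-06. The fertility difference of 5 gene lists differed between corpus and caput. Its median was higher in corpus by 0.222 for antioxidant genes (camera adjusted p = 0.00346; adjusted p = 0.675 with an estimated correlation) and 0.433 for interferon-stimulated genes (1.87e-06; adjusted p = 0.675 with an estimated correlation). It changed by -0.24 for smooth muscle (0.0438), -0.238 for macrophage (0.0237) and -0.366 for cell cycle genes (0.00565), each at adjusted p = 0.937 with an estimated correlation. Between cauda and caput it differed by 0.213 for antioxidant (0.00762), -0.321 for smooth muscle (0.00901), 0.228 for T and natural killer cell (0.0473), -0.352 for macrophage (0.00627) and 0.212 for protein folding genes (0.00627), each at adjusted p = 0.884 with an estimated correlation. Between cauda and corpus it differed by -0.247 for spermatid (0.00911; adjusted p = 0.936 with an estimated correlation), -0.318 for interferon-stimulated (4.57e-08; adjusted p = 0.366 with an estimated correlation) and -0.192 for fibroblast genes (0.00116; adjusted p = 0.884 with an estimated correlation). The same contrast gave -0.24 for nerve and Schwann cell (0.0306; adjusted p = 0.494 with an estimated correlation), 0.145 for protein folding (0.000586; adjusted p = 0.809 with an estimated correlation) and 0.255 for cell cycle genes (0.0023; adjusted p = 0.884 with an estimated correlation). Most of these list results rested on a few arrays. Without medium-low caput replicates 1 and 2, chosen after the values were seen, antioxidant (0.728 between corpus and caput, 0.966 between cauda and caput), macrophage (0.574 and 0.078), T and natural killer cell (0.966) and nerve genes (0.0526) did not pass. Without medium-low corpus replicate 2, chosen in the same way, spermatid (0.719), fibroblast (0.426), nerve (0.213), protein folding (0.0767) and cell cycle genes (0.0767) did not pass between cauda and corpus. Without the 3 arrays of a replicate number adjusted p reached 0.595 and 0.756 for smooth muscle, 0.636 for cell cycle genes between corpus and caput and 0.177 for protein folding between cauda and caput. Interferon-stimulated genes passed in each of these 8 settings, at adjusted p up to 0.00114 between corpus and caput and 0.000238 between cauda and corpus.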

How the results depend on the processing

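The settings without a pair of caput arrays, that without medium-low corpus replicate 2 for interaction lists, that with corpus and cauda arrays only and the test of replicate numbers were chosen after the data were seen. The segment counts stayed within 1.5 times of their values under each scaling, filter, weighting and left-out array that was run, except where given here, and no gene list of the 7 comparisons reversed. For interaction lists arrays were left out, with no other scaling or filter, and spermatid genes between cauda and corpus reversed, to a median of 0.071 without medium-low corpus replicate 2 and of 0.007 without the medium-low replicate 2 arrays (adjusted p = 0.719 and 0.981). Fertility counts moved most. With fewer or weighted arrays the number and spread of arrays changed by construction. The filters and 1 probe set per gene also removed called probe sets themselves, as given below. For the other changes the cause was not tested. Signal near the background limits the dim probe sets.

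Without probe sets below the lower quartile of signal the fertility count was 164 in caput, 0 in corpus and 0 over the segments, and without those below the median it was 948 in caput, 0 in corpus, 0 in cauda, 2 over the segments and 0 for the interaction. Both filters removed CCDC196. The filter at the median also removed MUC1, TLR5 and probe set 12708857. These probe sets could not be called there, so the counts of 0 are no test of them. With array medians subtracted it was 2 over the segments. Quantile normalization gave 25 and cyclic loess 35 in caput. Array weights, at 0.646, 1.64 and 0.246 for medium-low caput replicates 1, 2 and 3, gave 4976 in caput, 3 over the segments and 1738 for the interaction. A trended and robust prior gave 94 in caput and 2 over the segments. One probe set per gene gave 428 in caput, 2 over the segments and 0 for the interaction. That setting left out probe sets without a gene name, and so 12708857, the probe set called for the interaction. The arrays of a segment alone gave 2 in caput and 0 in cauda.

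With an unadjusted p under 0.05 and at least 2-fold, the counts were 805 in caput, 35 in corpus, 50 in cauda, 53 over the segments and 730 for the interaction. The segments gave 1115, 1586 and 1049 for corpus against caput, cauda against caput and cauda against corpus, 1266, 1875 and 1233 within high and 1251, 1622 and 926 within medium-low bulls. Segment differences of 1 fertility group alone, which are the within-group contrasts of the same model and no separate fit, gave 5240 for corpus against caput and 3881 for cauda against corpus in high bulls, and in medium-low bulls 4731, 5481 and 2715.

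Leaving out 1 array gave 2 to 4702 in caput, 0 to 7 in corpus, 1 to 5 in cauda and 1 to 2359 for the interaction. Leaving out the 3 arrays of a replicate number gave 0 to 462 over the segments. Without 1 array the counts were 3281 to 4484 for corpus against caput within high bulls. Within medium-low bulls they were 3074 to 5614 for corpus against caput and 1729 to 2471 for cauda against corpus. Without medium-low caput replicates 1 and 2, which leaves 1 array assumed to vary like the other groups, the counts were 3 in caput, 1 in cauda, 2 for the interaction, and 2841 and 3385 within medium-low bulls for corpus and cauda against caput. Without replicates 2 and 3 caput had 3511, and corpus and cauda arrays only gave 0 over the segments.

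Arrays with the same replicate number shared only a number in the labels. The deviations of 17 of 18 same-number pairs correlated above 0.1 (0.0706 to 0.55, against -0.39 to 0.114 for 36 other pairs), and 17 of 18 arrays correlated best with their own number, a hint from the data, not the design. In all, 395 probe sets differed between numbers, against at most 13 in 50 draws with shuffled numbers. With the replicate block the fertility count was 57, 1 and 2 in caput, corpus and cauda, where TLR5 fertility difference in cauda had an adjusted p of 0.0511, 2 over the segments with all 18 arrays and 8 there with no replicate block, and the segment counts were 10029, 9712 and 7459. A block whose number is shared by both fertility groups gave 10 in caput. For gene lists, leave-one-out removed the 3 arrays of a number, the block left the list test over the segments as it was, and the estimated correlation kept 2 of 52 calls.

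Single genes that reversed were among those that did not pass. CTCFL fertility difference in corpus was -0.014, -0.041 and -0.048 with medians subtracted, quantile and loess. ODF1 cauda against corpus was 0.016, 0.032, 0.069 and 0.216 with these and with weights, and 0.004 in medium-low bulls alone. SPATA3 cauda against corpus was 0.002, 0.012 and 0.025 with quantile, loess and weights, and 0.016 in high bulls alone, where SORD cauda against corpus was 0.146. Without medium-low caput replicates 1 and 2, CTCFL fertility difference in caput was 0.244. Without replicates 2 and 3 the fertility difference in caput was -1.163 for AKAP4, -1.586 for SMCP, -0.566 for SPATA3, -0.734 for TCP11, -1.605 for ODF1 and -0.549 for SPATA18. With corpus and cauda only, the fertility difference over the segments was 0.058 for C25H16orf89 and 0.101 for CTCFL. Leaving out 1 array, SMCP fertility difference in caput was -0.142 to 1.393, TCP11 fertility difference in caput -0.041 to 0.689 and ODF1 fertility difference in caput -0.265 to 1.217. In corpus the ranges were -0.28 to 0.582 for AKAP4, -0.334 to 1.337 for SMCP, -0.361 to 1.001 for ODF1, -0.068 to 0.062 for CTCFL, -0.048 to 0.429 for SPATA18 and -0.165 to 0.009 for SORD. In cauda AKAP4 was -0.18 to 0.289. Over the segments the 3 arrays of a replicate number were left out instead. There AKAP4 was -0.107 to 0.672, SMCP -0.048 to 1.025, ODF1 -0.071 to 0.858 and CTCFL -0.115 to 0.039. Without 1 array, cauda against corpus gave -0.096 to 0.739 for SMCP, -0.155 to 0.125 for SPATA3, -0.269 to 0.412 for ODF1 and -0.214 to 0.025 for SPATA18. Among named genes, 3079 values kept direction and side under the settings chosen first, 211 lost the call, 35 gained it and 43 reversed.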

Other observations

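Beside the lists that passed as sets, the segments differed in genes of lists that did not, and the values below were chosen after they were seen. HOX genes, which set position along the body axis, had 10 of 29 up and 7 down between cauda and caput (median 0.08, camera adjusted p = 0.888). HOXA9 rose by 3.35 (limma adjusted p = 1.97e-07) and HOXA10 by 2.15, while HOXC8 fell by 1.10 and HOXD8 by 1.07, and HOXA9 rose by 1.54 from caput to corpus. Antioxidant enzymes had 11 of 37 up and 11 down (camera adjusted p = 0.888), as GPX5 fell by 4.79 and GPX6 by 4.65 while GPX2 rose by 3.03 and glutathione reductase, GSR, by 2.37. Androgen and steroid genes had 7 of 24 up and 7 down (camera adjusted p = 0.888), among them SRD5A2, the enzyme that makes dihydrotestosterone, which fell by 3.46, and the androgen-responsive protease TMPRSS2, which rose by 2.81.

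Secreted proteins known for corpus and cauda had 10 of 23 up and 6 down between cauda and caput (camera adjusted p = 0.796), with CD52 at 5.68 against ELSPBP1 at -3.22 and WFDC8 at -3.08. The caput mean of WFDC8 mixes unlike arrays. WFDC8 was at 8.22 and 7.4 in medium-low caput replicates 1 and 2, 13.2 to 13.4 in the other caput arrays and 7.75 to 9.31 in cauda. Basal cell genes had 7 of 15 up and 2 down (camera adjusted p = 0.0842), with S100A2 at 1.64 and TRIM29 at -2.75. Acute inflammation genes had 10 up and 1 down (camera adjusted p = 0.0571), with SELP at 2.45, CCL2 at 1.37 and ICAM1 at 1.32. The claudin CLDN2 stood at -2.85, the carbonic anhydrase CA2 at -2.75 and the glial protein S100B at -2.71 in cauda against caput, and the chloride channel CFTR at -3.82 in corpus against caput.

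Other groupings of the same arrays were counted for each result. For corpus against caput 1 of 100 splits drawn, the real one, gave 8881 probe sets, and the highest other gave 2726. For cauda against caput 1 of 100 gave 8629 and the highest other 4401, and for cauda against corpus 1 of 100 gave 6511 and the highest other 2772. A share of 1 in 100 is the lowest these draws can give, so chance is unlikely for these 3 but not excluded. The draws treated arrays as exchangeable, though 6 bulls gave the arrays of all segments. The fertility results have only 10 splits each, too few for a share under 0.05. There, 1 of 10 gave as many in caput (57, highest other 16), 3 of 10 in corpus (1, highest other 1), 2 of 10 in cauda (3, highest other 6), 3 of 10 over the segments (1, highest other 3) and 3 of 10 for the interaction (1, highest other 1).

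Some genes had values that recurred in the arrays of 1 replicate number, chosen after they were seen and given with no explanation. ULBP3 stood at 9.63, 9.02 and 9.09 in the caput, corpus and cauda arrays of high replicate 2 and at 5.59 to 6.13 in the other arrays. LOC509034 stood at 8.12, 8 and 8.04 in medium-low replicate 1 and at 8.21, 7.93 and 7.81 in medium-low replicate 2, and at 5.16 to 6.12 elsewhere.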
